A study of Lotus japonicus with 6 samples.

How the data were processed

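Total RNA from leaves of Lotus japonicus (accession MG20, grown in vitro) was measured in 6 samples. Of these, 3 were labelled wild type and 3 were independent transgenic lines labelled as overexpressing LjMyb14 from a Lotus ubiquitin promoter. Each sample was hybridised to 1 array of a custom Agilent 1-colour (Cy3) design that carries transcription factor families and genes of secondary metabolism and defence, not the whole transcriptome.

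Per the file headers, each scan was read with Agilent Feature Extraction, whose version is given as 10.7.3.1 in the submitters' processing notes. The deposited intensity of a spot is background-subtracted and detrended within its array, per the file headers, and is not scaled between arrays. The deposited value table of the series held the same intensity in 91068 of 91068 cells, so as an alternative it amounts to leaving out the scaling between arrays. Its columns had median log2 values between 5.54 and 6.04. All arrays lay on 1 slide and carried the same scan time, so no slide or scan batch could be tested. The 3 wild type arrays and line 1 lay in row 2 of the slide and lines 2 and 3 in row 1, and this row was tested as a block.

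From these files, log2 of the processed intensity minus the array's 75th percentile over 14642 non-control spots was computed. The 75th percentile intensity ranged from 364 to 404 between arrays, and 71.7% to 78.0% of the spots were well above background. No spot was saturated, and spots with an outlier flag (32 to 78 per array) were left out. Spots of 1 probe were averaged, which gave 6358 probes with 3469 names. A probe was tested if it was well above background, in at least 0.5 of its spots, on at least 3 of the 6 arrays, which left 5039 probes of 2487 genes. Names sharing a locus identifier were taken as 1 gene. A name without one (an _est ending aside) counted as its own gene, so a gene under different names may be counted more than once. Where 1 probe per gene was needed, the probe with the highest mean over the arrays was used. Gene names are the array's own. The files used here give no probe sequence, genome build or description for them, and the reference table of gene symbols matched none of them, so positions are given only as the chromosome or clone within a name.

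Before averaging, arrays of a group were compared with the noise between spots of 1 probe on 1 array. Wild type arrays 1 and 3 differed by less than this noise: the variance of their difference was 0.444 times that expected from the spots, against 2.76 to 11.3 times for the other 5 pairs within a group. They were therefore averaged and counted as 1 sample, which leaves 2 wild type samples against 3 lines. The labels number them as separate wild type samples, and whether they came from the same RNA is not given. The design written before the data were examined counted all 6 arrays singly. That fit is given beside the main one, and the averaging was chosen after the data, including the counts of the 6-array fit, had been seen, and before any fit to 5 samples.

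Probes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 and called at a Benjamini-Hochberg adjusted p under 0.05, and fold changes are overexpressing lines over wild type. With 3 residual degrees of freedom plus 2.54 from the prior, the number of arrays limits the precision. On simulated data for this comparison (5039 probes, 5 runs, 100 probes changed per fold size and run), 13.8% of 2-fold and 63.6% of 4-fold changes were called, with a mean of 3.4 false calls per run. The simulated noise was independent between probes. Deviations that many probes of an array share were not simulated, so false calls on the real arrays may vary more. Gene lists were tested with limma camera at an inter-gene correlation of 0.01, adjusted over the 20 lists with at least 5 measured genes. In all, 30 lists were fixed as descriptions before the data were examined. Since the arrays carry only family codes, the codes of each list were written after the names, but not the values by group, had been seen, and 21 lists had names on the array. Lists for photosynthesis, ribosomal proteins, the shikimate pathway, terpenoids, the circadian clock, nodule or root, seed, xylem and epidermis had no codes and were not tested. Floral MADS-box genes were the only list for a tissue other than leaf. A probe not well above background on any array of a group has a bound only. For it, the other group's mean was set against, per array, the higher of the lowest signal well above background and the probe's own. The bound compares group means and leaves out the spread between samples, so it is not a confidence limit. Where the probe's own signal is the higher on every array, the bound equals the measured fold change.

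The genes named are LjMyb14, the 12 largest rises and 12 largest falls among called probes of at least 2-fold with all lines beyond all wild type arrays (1 probe per gene), and up to 4 genes with the smallest p per list. The ranking first used the brightest probe of each gene and was changed, after values were seen, to the most changed called probe, which is how the rule was written, and other probes of a gene are given for part of the genes only. Other genes are named as chosen after their values were seen. Alternatives were normexp background correction (on median spot and background signals with an offset of 50, as the files hold no mean signal of a spot), quantile and median scaling, the value table, other filters and variance models, array weights, a replicate block, the slide row as a block, other list tests and leaving out each sample. Counting 6 arrays singly, scaling on 8 E1A spike-in probes and leaving out wild type arrays 1 and 3 together were added after seeing the data.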

Results

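Leaf transcripts of 3 wild type Lotus japonicus arrays and 3 independent lines labelled LjMyb14 overexpressors were compared to find which regulatory and secondary-metabolism genes differ when this MYB transcription factor is expressed constitutively. Wild type arrays 1 and 3, though labelled as separate samples, differed by less than the noise between spots of 1 array. They were counted as 1 sample, so n is taken as 2 for wild type and 3 for the lines. Means are log2 signal relative to the array's 75th percentile, with SD over these samples, and p-values are from limma or camera with Benjamini-Hochberg adjustment.

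The probes named LjMYB14 did not show the labelled overexpression. At the tested probe the mean was -5.59 ± 0.55 (SD, n = 2) in wild type and -5.48 ± 0.76 (SD, n = 3) in the lines, a log2 fold change of 0.11 with a 95% confidence interval from -1.15 to 1.36 (adjusted p = 0.939). Line 2 was higher than the wild type mean by 0.97 and lines 1 and 3 differed from it by -0.21 and -0.45. This probe was well above background on 2 wild type arrays and 3 line arrays, and the other LjMYB14 probe on none and 1, so both lie near background. Whether the probes lie within the introduced sequence is not given in the sources used here, so they may not check the labels. Another MYB gene, LjMYB76a, had the largest rise on the array: it rose by 7.54 on the log2 scale, or 186-fold, at its brighter probe (from -1.69 ± 0.13 to 5.85 ± 0.14; adjusted p = 0.000189) and by 7.68 at the other. The rise at the brighter probe was 7.46, 7.70 and 7.45 in lines 1, 2 and 3. The lines are called by their label below, with no statement that LjMYB14 itself was raised.

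**Figure D1:**
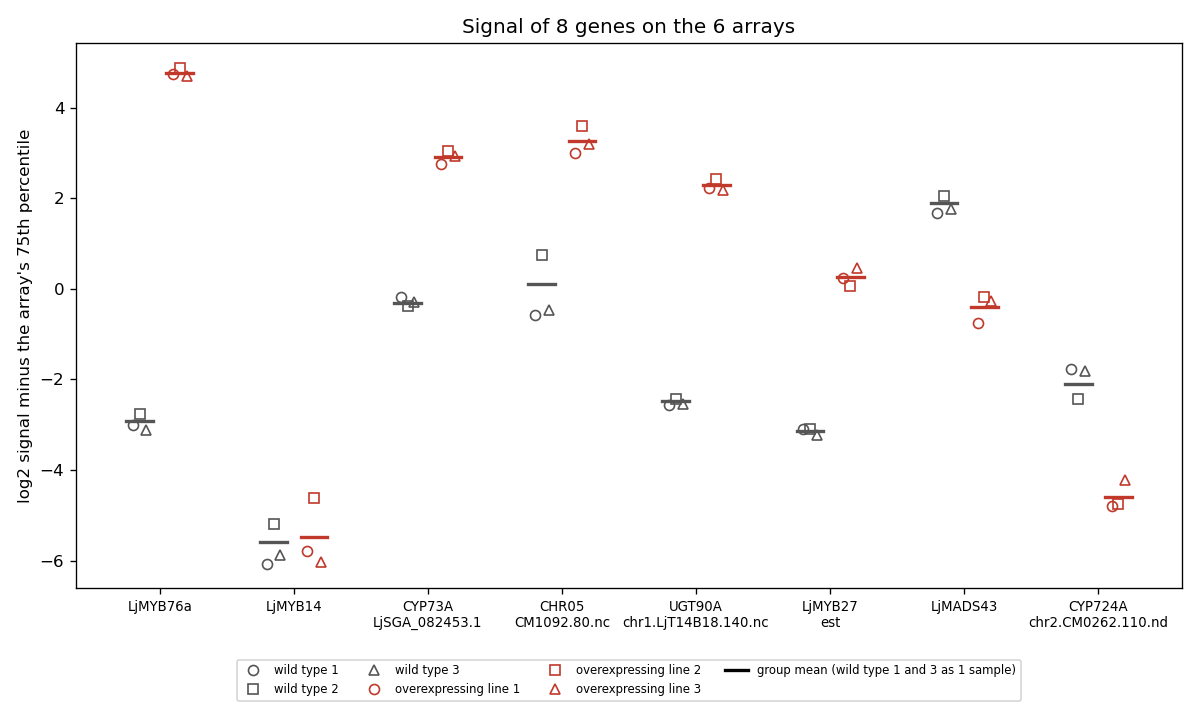
Log2 signal minus the array's 75th percentile (vertical axis) for 8 genes (horizontal axis) on the 3 wild type arrays (grey) and the 3 overexpressing lines (red), with group means as bars. LjMYB14 overlaps between groups, while at the LjMYB76a probe with the largest change the lines lie 7.68 above wild type.

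In all, 116 probes rose and 57 fell in the lines, each by at least 2-fold, out of 5039 tested. By the brightest probe of each gene, 55 genes rose and 27 fell out of 2487. Large rises also occurred in glycosyltransferases, enzymes that attach sugars to small molecules, and in a transporter. Neighbouring genes on chromosome 1 clone LjT14B18, UGT90A_chr1.LjT14B18.140.nc and UGT92A_chr1.LjT14B18.160.nc, rose 27.2-fold (-2.49 ± 0.08 to 2.28 ± 0.13; adjusted p = 0.00100) and 25.1-fold (-4.43 ± 0.01 to 0.21 ± 0.02; adjusted p = 0.000949). UGT92A_LjT30N24.300.nd rose 29.2-fold (adjusted p = 0.0138) and UGT71B_LjSGA_128268.1 rose 5.50-fold at its brightest probe (adjusted p = 0.00830) and 10.1-fold at a dimmer one, well above background on 2 of 3 wild type arrays (adjusted p = 0.0288). At probes not well above background in wild type, the bound on the rise was 26.4-fold for the transporter MDR016_chr6.CM0118.100.nd and 11.7-fold for ugt72B5_ntc. It was 7.17-fold for LjWRKY39 and 6.89-fold for the cytochrome P450 CYP71D_LjT06P13.200.nd. Such a bound, written "at least" below, compares group means, leaves out the spread between samples and is not a minimum for the gene. For CYP71D_LjT06P13.200.nd the log2 changes at this probe were 4.65, 4.02 and 2.72 in lines 1, 2 and 3. At brighter probes, well above background on all arrays, MDR016_chr6.CM0118.100.nd rose 4.91-fold (adjusted p = 0.0427) and ugt72B5_ntc rose by 2.45 on the log2 scale. The other probe of LjWRKY39 gave a log2 fold change of 1.1. UGT92A_LjT44J06.210.nd was at least 8.77-fold higher at 1 probe, but its other probe gave -0.268. LjBGLU4_ntc rose 11.2-fold at 1 probe (adjusted p = 0.04997), with 0.614 on the log2 scale at the other. Without wild type array 2 the log2 fold change of the first was 2.55 (adjusted p = 0.236), and without wild type arrays 1 and 3 it was 4.42 (adjusted p = 0.115). In the same settings the dimmer UGT71B_LjSGA_128268.1 probe gave 4.11 (adjusted p = 0.0425) and 2.56 (adjusted p = 0.115). LjMYB27_est rose 10.5-fold (adjusted p = 0.00396) in all lines, by 3.38, 3.19 and 3.60 on the log2 scale.

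The largest falls included cytochrome P450 genes and glycosidases. CYP88A_chr2.CM0021.680.nc, of the family that includes ent-kaurenoic acid oxidases of gibberellin synthesis, was at least 7.45-fold lower (adjusted p = 0.00396) at 1 probe, where the lines were not well above background, and fell by 3.43 on the log2 scale at the other, well above background on 1 line array. PEN2_LjSGA_069328.1.1 was at least 11.8-fold lower (adjusted p = 0.0288) and BGLU7_LjSGA_016061.1 at least 7.36-fold lower (adjusted p = 0.00886), and at these probes the lines were not well above background. The brighter BGLU7_LjSGA_016061.1 probe, well above background on 2 line arrays, gave a log2 fold change of -2.33 with an adjusted p of 0.105. The probes of the same locus named BGLUG2_LjSGA_069328.1.1, also not well above background in the lines, were at least 9.84-fold and 6.59-fold lower, while its brightest probe, well above background on 2 line arrays, gave -2.37 with an adjusted p of 0.112. CYP716A_LjSGA_137705.1, of a family of triterpenoid oxidases, fell 7.38-fold from 1.68 ± 0.90 to -1.20 ± 0.57 (adjusted p = 0.0498). Its call ended whichever array was left out, and its log2 fold change was -3.52 without wild type array 2 (adjusted p = 0.131) and -2.25 without wild type arrays 1 and 3 (adjusted p = 0.286). The adjacent CYP724A_chr2.CM0262.110.nd and CYP724A_chr2.CM0262.120.nd fell 5.60-fold and 5.50-fold (adjusted p = 0.0253 and 0.0288), and the transporter MDR148_chr2.CM0308.320.nc fell 7.39-fold at 1 probe and by 1.34 on the log2 scale at the other. BGLUG2_LjSGA_034905.1 fell 9.53-fold and BGLUG2_LjSGA_050606.1 fell 7.62-fold, with 1 line array each well above background, and CYP94A_chr2.CM0788.120.nc fell 6.29-fold with 2. FHYD09_LjT16L08.100.nd was at least 4.03-fold lower at 1 probe and at least 3.12-fold at its brighter one, and LjMADS43 fell 4.87-fold (adjusted p = 0.0218).

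These counts rest on few samples. With all 6 arrays counted singly, 342 probes rose and 297 fell, and with the slide row as a block 2 rose and 0 fell (limma; 618 at an unadjusted p under 0.05), both of them LjMYB76a. In that block the wild type arrays share their row with line 1 only, so it sets 1 line against wild type and cannot show whether the row moved the other calls. Without wild type array 2 the counts were 7 and 1, without wild type arrays 1 and 3 together 4 and 0 (504 at an unadjusted p under 0.05), without line 1 13 and 1, without line 2 272 and 167, and without line 3 47 and 30. Only LjMYB76a, UGT90A_chr1.LjT14B18.140.nc and UGT92A_chr1.LjT14B18.160.nc kept a called probe in every one of the 7 settings that left out arrays. Scaled on spike-in probes, 13 rose and 10 fell, and the median of all probes moved by -0.24. On these E1A probes line 2 stood apart, at 2.88 above its 75th percentile against 1.72 to 2.10 on the other arrays. All 173 called probes separated the 3 lines from the 3 wild type arrays. Of all tested probes, 39.5% separated the 3 lines from the 2 wild type samples, where the average over all such splits of the samples is 20%. Probes can deviate together on an array, and the shares of the other splits were not computed, so no conclusion is drawn from this.

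Genes of the general phenylpropanoid steps, which make the precursors of flavonoids and lignin, rose as a group. Here and in the lists below, counts of genes are at the brightest probe of each. Of 35 measured, 10 rose and none fell (21 and 0 adjusted over the list alone), and the median log2 fold change was 1.14 (camera adjusted p = 3.4e-12; adjusted p = 0.240 with an estimated correlation). The median was 1.06, 0.87 and 1.03 in lines 1, 2 and 3. CYP73A_LjSGA_082453.1 (also on the array as C4H03), a cinnamate 4-hydroxylase, rose 9.29-fold from -0.31 ± 0.10 to 2.91 ± 0.15 (adjusted p = 0.00396), and C4H05_LjSGA_031602.1 rose 3.03-fold (adjusted p = 0.0223). CoumLig16_chr6.CM0057.160.nc and CoumLig1_chr2.CM0018.1240.nc, whose code is read here as coumarate ligase, rose 2.72-fold and 2.63-fold. Of the 15 measured genes with this code only 3 rose, 5 had a negative fold change and the median was 0.15. Of 14 genes coded PAL, phenylalanine ammonia-lyase, 4 rose and 13 had a positive fold change, with a median of 1.14. PAL, C4H and CHS genes have close copies whose signals the probes may share.

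The isoflavonoid and vestitol list, which covers the legume branch toward the phytoalexin vestitol, was also higher, but not across all its families. Median log2 fold changes were 0.63 for 28 genes coded CHS, 0.97 for 6 CHR, 0.55 for 5 PKR and 0.62 for 6 CHI. They were -0.13 for 7 HID, 0.29 for 8 IFR and -0.05 for 3 VR genes. For 9 I2H or CYP81E, 4 CYP93C and 2 PTR genes they were -0.33, 0.08 and -0.11. The call of the list therefore does not show that every part of this branch rose. Of 78 genes, 6 rose and none fell (11 and 0 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.000112; adjusted p = 0.716 with an estimated correlation). The adjacent chalcone reductase genes CHR05_CM1092.80.nc and CHR04_CM1092.70.nc rose 8.94-fold and 8.93-fold (adjusted p = 0.0288 and 0.0309), although wild type array 2 lay above the other wild type arrays for both (0.74 against -0.57 and -0.48 for CHR05). Signals of the 2 genes were nearly the same on every array, such as 3.00 and 2.96 on line 1 and 3.60 and 3.58 on line 2. Their probes may share signal, so these genes may not be separate among the 6 that rose. Without wild type array 2 their log2 fold changes were 3.79 and 3.84 (adjusted p = 0.0643 for each), and without wild type arrays 1 and 3 they were 2.53 and 2.48 (adjusted p = 0.156 and 0.162). CYP81E_chr2.CM0250.70.nc, also coded I2H1, rose 3.73-fold (adjusted p = 0.0218) and IFR4_, an isoflavone reductase code, rose 3.23-fold (adjusted p = 0.0208). The other 2 genes that rose, named after their values were seen, were VR1_chr1.CM1255.320.nc (log2 fold change 2.52) and HID3 (1.73). None of 28 genes coded CHS, chalcone synthase, was called at its brightest probe, and 20 had a positive fold change. A dimmer probe of CHS08_chr2.CM0018.1080.nc rose by 1.83 on the log2 scale (adjusted p = 0.0237), while its brightest gave 1.23 (adjusted p = 0.0568).

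The neighbouring branches, as these lists define them, did not rise as groups. Genes coded CHS were counted in the isoflavonoid list and not in these. The contrast between the lists therefore does not show a rise limited to the isoflavonoid branch. In the flavonol, anthocyanin and proanthocyanidin list of 53 genes, LDO02_chr1.LjB18K24.120.nd rose 3.09-fold (well above background on 2 wild type arrays), FHYD09_LjT16L08.100.nd was lower, and the list was not called (median -0.05, adjusted p = 0.770); the counts were the same adjusted over the list alone. In the lignin branch, 2 of 46 genes fell and none rose (4 and 0 adjusted over the list alone), both laccases: LAC20_LjSGA_027663.1 fell by 1.69 and LAC02_chr1.CM0147.770.nc by 1.59 on the log2 scale (adjusted p = 0.0459 for each). The log2 fold changes of the laccases LAC04_chr1.CM0147.300.nc and LAC19_LjSGA_022002.1 were -1.40 and -1.87, with adjusted p of 0.0626 and 0.0732, and a dimmer LAC04_chr1.CM0147.300.nc probe fell by 1.51 (adjusted p = 0.0455). The lignin list as a whole was not called (median -0.21, adjusted p = 0.201).

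**Figure D2:**
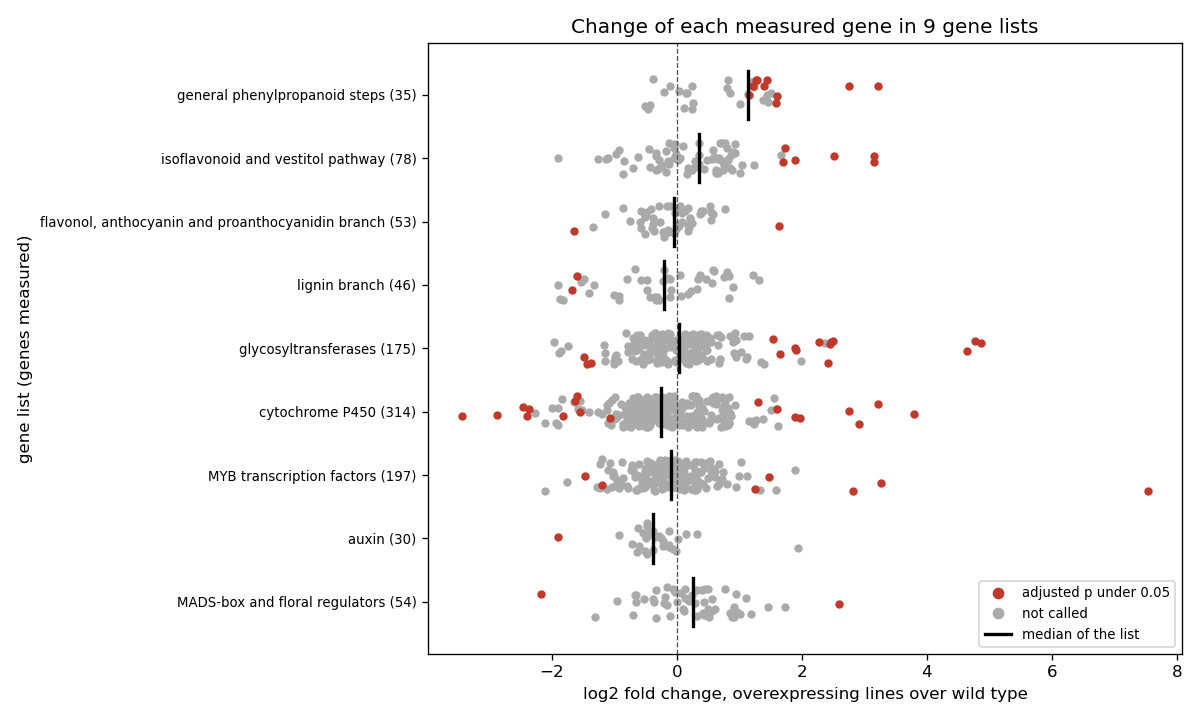
Log2 fold change of the overexpressing lines over wild type (horizontal axis) for every measured gene, at its brightest probe, in 9 gene lists (vertical axis, number measured in brackets). Red points passed an adjusted p under 0.05, grey points did not, and bars mark medians, which are 1.14 for the general phenylpropanoid steps and -0.38 for auxin.

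Among enzyme families of mixed function, 12 of 175 glycosyltransferases rose and 3 fell (18 and 6 adjusted over the list alone), with a median of 0.03, and the list was not called (adjusted p = 0.0907). UGT71B_LjSGA_066183.1 rose 5.67-fold (adjusted p = 0.00726), with 1.22 on the log2 scale at its other probe, well above background on 1 wild type array (adjusted p = 0.547). Of 314 cytochrome P450 genes, 8 rose and 10 fell (9 and 12 adjusted over the list alone; median -0.26, adjusted p = 0.144). The lists overlap. These rises include CYP73A_LjSGA_082453.1, C4H05_LjSGA_031602.1 and CYP81E_chr2.CM0250.70.nc, already counted in the phenylpropanoid and isoflavonoid lists. Of 159 ABC and MATE transporters, 3 rose and 2 fell (5 and 2 adjusted over the list alone; median -0.16, adjusted p = 0.770), with MDR125_chr2.LjT13P17.10.nd up 3.06-fold and MDR131_LjSGA_125461.1 up 4.59-fold.

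The auxin list, made of AUX-IAA repressors and auxin response genes, was lower: 1 of 30 genes fell and none rose, also adjusted over the list alone, and the median was -0.38 (camera adjusted p = 0.00600; adjusted p = 0.716 with an estimated correlation). LjAUX-IAA17 fell 3.73-fold (adjusted p = 0.0498), while the log2 fold change of LjAUX-IAA16 was 1.95 with an adjusted p of 0.0795. The MADS-box and floral list, the only list tested for another tissue, was higher (median 0.26, camera adjusted p = 0.0148; adjusted p = 0.716 with an estimated correlation), but its genes went both ways. LjMADS19 rose 6.03-fold (adjusted p = 0.00741) and LjMADS43 fell, and of 54 genes these 2 were called (2 higher and 1 lower adjusted over the list alone). With normexp background correction its median was -0.03 and its adjusted p 0.723. Both calls ended without line 3, at adjusted p of 0.0739 for auxin and 0.0862 for the MADS-box list.

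The MYB, heat shock factor, WRKY, AP2/ERF, NAC and bHLH families changed in single members and were not called as lists. Of 197 MYB genes, 5 rose and 2 fell (7 and 4 adjusted over the list alone; adjusted p = 0.770), with LjMYB65_est up 7.06-fold (adjusted p = 0.0117) and LjMYB81a down 2.76-fold (adjusted p = 0.0268). Of 18 heat shock factors, 2 rose (3 adjusted over the list alone; adjusted p = 0.111): LjHSF16 by 3.37-fold and LjHSF14 by 9.02-fold, the latter well above background on 1 wild type array and with 0.678 on the log2 scale at its other probe. Of 61 WRKY genes, 1 rose and 2 fell at the brightest probe, which leaves out the dimmer LjWRKY39 probe given above (1 and 3 adjusted over the list alone; adjusted p = 0.889), with LjWRKY66_est up 4.08-fold, LjWRKY7 down 2.24-fold and WRKY_05_LjT10J09.60.nd down 2.21-fold. The log2 changes of LjWRKY7 in lines 1, 2 and 3 were -1.13, -1.26 and -1.10, and those of WRKY_05_LjT10J09.60.nd were -1.12, -1.24 and -1.07. LjWRKY7 carries no locus identifier, so whether both names stand for 1 gene cannot be told. Of 119 AP2/ERF genes 2 rose, LjERF41 by 5.67-fold and LjERF39 by at least 3.57-fold (adjusted p of the list = 0.610). The log2 fold change of LjERF41 was 2.50, against 3.18 without wild type array 2 (adjusted p = 0.0674) and 1.82 without wild type arrays 1 and 3 (adjusted p = 0.199). Of 90 NAC genes, LjNAM12 rose 6.23-fold and LjNAM11_est fell 2.83-fold (adjusted p of the list = 0.875). Of 110 bHLH genes, LjbHLH52 was at least 3.04-fold higher (adjusted p of the list = 0.148). None of these 3 lists had a gene called when adjusted over the list alone. For the AP2/ERF and NAC lists the median was negative (-0.06 and -0.11) while the mean and the test pointed up.

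No gene was called, over all probes, among 40 bZIP, 70 homeobox, 88 defence and immune receptor, 10 jasmonate and 7 cell cycle genes, at the brightest probe of each. Their adjusted p as lists were 0.770, 0.770, 0.993, 0.770 and 0.0872, and adjusted over the list alone 1 cell cycle gene rose. The median of the defence list was -0.05 while its test pointed up. Its count leaves out the dimmer called probes of PEN2_LjSGA_069328.1.1 given above. The list of peroxidases and glutathione transferases had 4 measured genes, none called, and was not tested.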

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

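The fold changes of all 173 called probes kept their sign under every alternative that tested them, and no called list or named call changed its tested direction, though the median of the MADS-box list went from 0.26 to -0.03 with normexp. For the probes this was largely fixed by the calling. All 173 changed by at least 2-fold and had all lines beyond all wild type arrays, so leaving out arrays could not turn a sign. How many probes passed depended strongly on the fit. Beside 116 higher and 57 lower, the counts were 342 and 297 with all 6 arrays counted singly, 2 and 0 with the slide row as a block, and 13 and 10 with spike-in scaling (56.5% higher against 67.1%). Array weights, whose estimation did not converge, gave 792 and 1032. An intensity trend with robust moderation gave 195 higher, no filter gave 24 lower, and the value table without scaling gave 37 lower. Leaving out arrays gave 4 to 272 higher and 0 to 167 lower, with 7 and 1 without wild type array 2, and in 2 of these settings the lone wild type sample is assumed to vary like the lines. The cause of these differences was not tested.

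Whether replicate numbers pair the samples was not settled. Same-numbered deviations correlated only at 0.01, 0.17 and 0.07, yet 4 of 6 samples correlated best with their own number. These measures point different ways, so no conclusion on pairing is drawn. A replicate block could be fitted only with all 6 arrays counted singly, and gave 235 higher and 138 lower.

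Among the camera settings, the general phenylpropanoid list ended its call only with an estimated correlation (adjusted p = 0.240). With fry, which tests a list against no change and not against the other genes, its adjusted p was 0.0482. For the isoflavonoid, auxin and MADS-box lists the estimated correlation gave 0.716 each, and fry 0.196, 0.136 and 0.196. The MADS-box list also lost its call with normexp (0.723), no filter (0.103) and without line 3. Over the settings that left out arrays, adjusted p ran from 2.7e-12 to 4.0e-10 for phenylpropanoid, 8.9e-09 to 0.0336 for isoflavonoid, 0.00339 to 0.0739 for auxin and 0.0159 to 0.0862 for MADS-box genes. Of the lists not called, 4 passed at least once, 9 times in all, with glycosyltransferases 5 of these times. LjMYB14 was not called under any alternative (log2 fold change -0.33 to 0.50). Dim signal limits LjMYB14 and the genes given as bounds.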

Other observations

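The tests in this part were chosen after the results had been seen, except the splits of the samples for the 6-array fit and for the number of called lists, whose values had not been seen when they were written (those of the called probes of 5 samples had).

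Beyond the fixed lists, 28 further code families with at least 5 measured genes were tested with camera, and none was called. The lowest adjusted p was 0.137, for 6 genes coded BGLUG (median log2 fold change -0.92, 1 fall), against 0.982 with an estimated correlation. Among P450 subfamilies, 15 of 17 genes coded CYP82A had a positive fold change, with a median of 0.67 and 1 call, and all 4 genes coded CYP724A had a negative one, with a median of -2.24 and 2 calls. Of 28 genes coded UGT71B, 5 rose and none fell, and of 26 laccases 2 fell and none rose. The 8 CHS genes on contig CM0018 of chromosome 2 had log2 fold changes from 0.57 to 1.23 at their brightest probes, none of these called. Of 25 control probes well above background on all arrays, 0 had all 3 lines above all 3 wild type arrays and 1, (+)eQC-40, had all 3 below (8.16, 8.48 and 8.27 against 8.55, 8.63 and 8.57). The control probe ETG09_48764 read -8.35 on line 2 and between -3.65 and -1.97 on the other 5 arrays.

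The array's LjMYB14 did not rise while LjMYB76a did in every line. A line array that held wild type leaf is argued against, since the lowest line lay 7.35 log2 units above the highest wild type array at LjMYB76a. A candidate explanation is that LjMYB76a is the array's name for the introduced gene, whose rise exceeded that of the next gene by 2.67 log2 units. An endogenous gene that responds to the transgene would give the same value, so these cannot be told apart without probe sequences. A 4-fold rise of LjMYB14 lies above its upper 95% bound of 1.36 log2 units, but its probes are too near background to exclude one.

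Line 2 lay apart from lines 1 and 3, and more probes were called without it (272 higher, 167 lower). Whether LjMYB76a was lower in line 2 cannot be told, since the sign depends on the scaling. With the main scaling, line 2 was higher than the mean of the others by at least 0.16 at both LjMYB76a probes. Relative to the E1A spike-ins it was lower at both. Less labelled leaf RNA on the array of line 2 may contribute, as its E1A spike-ins lay 0.98 log2 units above the mean of the other lines. Whether this moved single genes cannot be told apart from a difference between independent lines, since each line is 1 sample.

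Genes of the general phenylpropanoid steps rose together in the lines labelled LjMyb14 overexpressors. An effect of the introduced gene is the biological explanation the design gives, and it is untested here. Array scaling is argued against, as the lowest median of the list over 5 other scalings was 0.77. The largest and smallest fold changes of 6 genes coded C4H or CYP73A lay 5.06 standard errors apart. Probes that read 1 transcript to different degrees can also differ in fold change, so this distance cannot exclude a shared transcript. For 13 PAL genes with a positive fold change the distance was 2.57 standard errors. Separate genes and a shared transcript cannot be told apart in either family.

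With 10 splits of the samples no share under 0.05 can be reached. The real split gave 173 called probes and the highest other 0, and with 6 arrays counted singly these were 639 and 0. In each case 1 split, the real one, reached the value. For the number of called lists, 4 of the 10 splits gave at least the 4 of the real split, with a highest of 6. For single lists, the adjusted p of the real split and the smallest other were 3.4e-12 and 1.2e-06 for phenylpropanoid, 0.00600 and 0.0151 for auxin and 0.0148 and 0.0283 for MADS-box genes, each reached by 1 split. For the isoflavonoid list they were 0.000112 and 6.3e-10, and 3 of the 10 splits reached the real value, the smallest with wild type arrays 1 and 3 and line 1 against the rest.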
